A study of Homo sapiens with 8 samples.

How the data were processed

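Single cells of human adipose tissue were sorted by flow cytometry and sequenced with the 10x Genomics Chromium 3' assay, per the labels' protocols. The 8 libraries cover 4 sorted populations from lean and from obese donors: CD200R-negative natural killer (NK) cells, CD200R-positive innate lymphoid cells (ILC), dendritic cells (DC) and macrophages. Each group holds 1 library. How many donors contributed to a library is not given in the sources used here.

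The deposited values are whole-number counts of unique molecular identifiers (UMIs) per gene and cell barcode, with no normalization by the authors. Cell Ranger was used, per the submitters' processing notes, which give no version. These notes name mm10, a mouse build, while the gene identifiers in the files are human Ensembl identifiers, so no coordinates are printed. Of the 33538 identifiers, 33456 were named with GENCODE 29 and 82 had no symbol there. A set of 741 genes whose expression can mark a person was left out of every gene-level table and of the clustering, which kept 32797 genes. That set covers sex-linked transcripts, KIR genes, polymorphic HLA genes, receptor variable segments and a few genes with common deletions.

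The smallest barcode held 500 UMIs, so the deposited tables had been filtered on barcodes before this work. Cells were kept with at least 200 genes detected, at most 20% mitochondrial UMIs and no doublet call. Scrublet, run per library through scanpy, called 118 of 27159 cells (0.434%). That is too few for the caller to have worked, and doublets of like cells cannot be seen by it, so doublets stay in the data to an unknown extent. The filters kept 4320 of 5126 barcodes in the lean and 3855 of 4250 in the obese NK sort, 3666 of 3740 and 2799 of 2985 in the ILC sort, 3317 of 4437 and 3699 of 5421 in the dendritic cell sort, and 2558 of 2883 and 2827 of 4295 in the macrophage sort. Median UMIs per kept cell were 5881.5 and 5175 in the lean and obese NK sorts, 5942.5 and 6491 in the ILC sorts, 14770 and 17633 in the dendritic cell sorts, and 5402.5 and 15822 in the macrophage sorts.

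UMIs of kept cells were summed per library and divided by the library total and given in the usual unit CPM, which sets that total to 1e6. Obese and lean libraries of a sort were compared, and within each donor condition the CD200R-positive with the CD200R-negative sort and the dendritic cell with the macrophage sort. A comparison is the log2 ratio of CPM after adding 1 CPM to both values. With 1 library per group there is no test, standard error or count of differing genes. CPM values carry exact Poisson intervals and cell shares exact Clopper-Pearson binomial intervals, both at 95%. These cover counting error only.

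The gene lists, the cell type markers and the rule for named genes were fixed before the data were examined, as were the comparisons and the alternatives, apart from those named below as added later. There are 25 lists: cytotoxic effector, NK tissue residency, lymphocyte cytokines and chemokines, ILC2 identity, ILC3 identity, ILC core, conventional DC identity, DC maturation, MHC class II presentation, macrophage core, perivascular macrophage, lipid-associated macrophage, inflammatory myeloid, monocyte, interferon response, immediate early and heat shock, hypoxia and glycolysis, TNF and NF-kB targets, metallothionein, fatty acid oxidation, oxidative phosphorylation, TGF-beta response, proliferation, mitochondrial transcripts and ribosomal proteins. The list gene SOD2 has no unique identifier under its symbol and was not used. A list is described by the median log2 ratio of its members with at least 20 UMIs in both libraries together, and by the percentile of that median among 10000 random lists of the same size. Random members came from the 201 genes nearest in mean expression.

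Named genes were those at 100 CPM or more in the higher library, with a UMI in at least 10% of its kept cells, that had the 10 highest or 10 lowest log2 ratios. Between sorts, the sign had to be shared by the lean and obese libraries. Up to 4 members of each list with the highest mean CPM were named too. For the genes named by ratio, the interval of the value in the higher library reached at most 5.06% to either side. The counting interval of their obese-lean log2 ratio reached at most 0.23 to either side of its own midpoint. That midpoint need not be the printed ratio. For MT1G in the macrophage sort the interval ran from -6.20 to -5.92, with a printed ratio of -5.93.

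For cell classes, counts were scaled to 10000 UMIs per cell and log-transformed. The 2000 most variable genes gave 30 principal components and a graph of 15 neighbours, partitioned by Leiden at resolution 1.0. Lymphoid and myeloid libraries were clustered apart, without integration. A cluster was given the class with the largest part of its markers detected in at least 25% of the cells and at least 1.2-fold above the other clusters, with 3 such markers as the minimum. Clusters led by proliferation genes, clusters of low depth without a marker of the class among their 10 leading genes, and clusters where another class had more markers among these stayed unnamed. The rules that leave a cluster unnamed were set after the data had been seen. A cluster was called stress-led when at least 3 of its 10 leading genes were heat shock or metallothionein genes. A cluster with markers of several DC types was counted as DC of mixed type and added to the dendritic cell class, which the plan had not provided for. The largest cluster of each sort's own class was not the same in the lean and obese libraries. It was led by ABI3 and FGFBP2 in the lean and by GZMK and TIGIT in the obese NK sort, by TMPRSS11E and NEB against PCDH9 and LST1 in the ILC sort, by FCER1A and CD69 against BCL7A and GPAT3 in the dendritic cell sort, and by TTN and RNASE1 against CCL3L1 and EGR1 in the macrophage sort.

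Alternatives were TMM scaling between the 2 libraries (edgeR), totals without mitochondrial and ribosomal protein genes, all barcodes, equal weight for each cell, cells thinned to 1000 UMIs, cells of the own class alone, no minimum count, a pseudocount of 10 CPM, resolutions 0.5 and 2.0, all 8 libraries clustered together, and doublet calls kept. Thinning left out 50 and 13 cells of the lean and obese NK sorts, 7 and 4 of the ILC sorts, 115 and 19 of the dendritic cell sorts, and 84 and 36 of the macrophage sorts. The alternatives without clusters led by heat shock and metallothionein genes, and with stress genes left out of the clustering, were added after seeing the data. Stress genes here were the heat shock, metallothionein and immediate early genes, with SLC30A1, HMOX1, BAG3 and MTRNR2L genes.

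The comparison step was tested on simulated data: Poisson counts from the means of the lean library, at the depths of both libraries. For each obese-lean comparison, 200 genes were made higher or lower by 1 log2 unit. These genes, and those of the lists without a difference, were drawn from genes with at least 200 UMIs in the lean library. In the lists with a difference every member was raised. Recovery of genes at lower counts, of smaller differences and under spread beyond counting error was thus not tested. The comparisons between sorts used the same code and were not simulated. It ran on 14466 genes for the NK sort, 13801 for the ILC sort, 15647 for the dendritic cell sort and 15418 for the macrophage sort, and in each sort 100% of the simulated genes came back within 0.5 log2. In each sort 10 of 10 simulated lists with a difference lay above the percentile 97.5. Of 10 simulated lists without one, 10 lay inside the central range in the NK, dendritic cell and macrophage sorts and 9 in the ILC sort. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.

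Genes with near-identical copies share reads, so the levels of CCL3L1, CCL4L2, the MT1 genes, HSPA1A, HSPA1B, HBA1, HBA2 and the MTRNR2L genes, which resemble mitochondrial ribosomal RNA, are uncertain as single genes.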

Results

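Immune cells were sorted from human adipose tissue of lean and obese donors, and their transcripts were counted cell by cell. The lean and obese libraries held 28135345 and 23448287 UMIs in the CD200R-negative natural killer (NK) sort and 22827190 and 19412016 in the CD200R-positive innate lymphoid cell (ILC) sort. They held 51912836 and 70139888 UMIs in the dendritic cell sort and 14919362 and 47198871 in the macrophage sort. Each group had 1 library, so no difference has a replicate check, and each compares the libraries rather than the donor conditions. Log2 ratios are of CPM with 1 CPM added, obese over lean unless stated. Percentiles place a list's median among 10000 random lists matched on mean expression.

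The sorts held the cell types they were labelled for, to differing degrees. NK-like cells made up 96.7% (95% interval 96.1 to 97.2, exact binomial, counting error only) of the lean and 85.8% (84.6 to 86.8) of the obese CD200R-negative sort. This gap of -10.95 percentage points was -3.83 with all 8 libraries clustered together, and unnamed clusters held 1.37% of lean and 9.91% of obese cells. These clusters were led by proliferation genes or by HBA1 and HBA2 beside NK genes, so the gap need not be a loss of NK cells alone. ILC-like cells made up 95.2% (94.5 to 95.9) and 94.5% (93.5 to 95.3) of the CD200R-positive sort, with overlapping intervals. Dendritic-like cells made up 77.9% (76.5 to 79.3) and 75.8% (74.3 to 77.1) of the dendritic cell sort, with cDC2-like cells, the conventional type specialised in priming helper T cells, the most frequent at 42.7% and 39.4%. Macrophage-like cells were only 38.1% (36.2 to 40) and 41.1% (39.2 to 42.9) of the macrophage sort. The difference of 2.99 percentage points turned to -6.48 at resolution 0.5 and -5.76 with all 8 libraries clustered together, so its direction is not settled. The sort gates and the gap in depth, widest in the macrophage sort, can set such shares. CD200R1, which encodes the receptor used for sorting, stood at 57.6 CPM (54.6 to 60.9) and 62 CPM (58.6 to 65.7) in the lean and obese CD200R-positive libraries against 6.84 (5.89 to 7.9) and 9.78 (8.53 to 11.2) in the CD200R-negative ones.

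**Figure D1:**
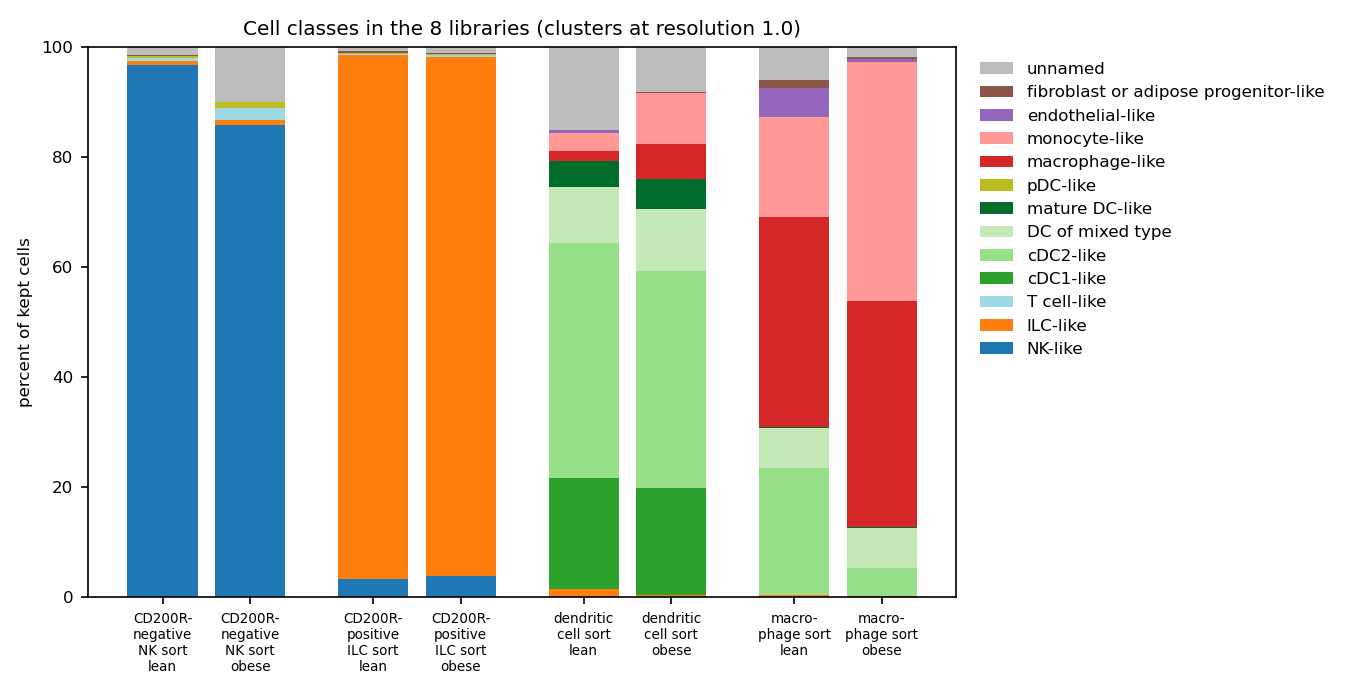
Stacked bars give the percent of kept cells in each cell class, 1 bar per library, with clusters left unnamed in grey. NK-like cells fill 96.7% and 85.8% of the CD200R-negative bars, and macrophage-like cells 38.1% and 41.1% of the macrophage bars.

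In the CD200R-negative NK sort, the question is how adipose NK cells of lean and obese donors differ. The genes of cell killing were lower in the obese library. All 13 measured members of the cytotoxic effector list had lower CPM there, with a median log2 ratio of -0.56 at percentile 0. GNLY, which encodes the pore-forming granulysin, stood at 6937 CPM (6906 to 6969) in the lean and 5589 CPM in the obese library. NKG7 stood at 2934 and 1987 CPM, and the serine protease gene GZMB at 1947 and 1301. The chemokine genes CCL4 (5825 and 3449 CPM) and CCL3 (929.6 and 493 CPM) were lower as well. Within NK-like cells alone the cytotoxic median was again -0.56.

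Genes of tissue-resident and ILC-related programs were higher in the obese NK sort. The NK tissue residency list had a median of 0.22 with 9 of 12 members higher (percentile 99.7), and its member GZMK, a granzyme of less mature NK cells, stood at 361 CPM in the lean and 497 CPM in the obese library. The ILC core list had a median of 0.32 with 12 of 13 members higher (percentile 99.99), among them IL7R, the receptor for a lymphocyte survival cytokine, at 519.9 and 664 CPM. The ILC3 identity list had a median of 0.48 with 9 of 9 higher. The TNF and NF-kB target list had a median of 0.43 and included NFKB1 at 613 and 828 CPM. CD83 (130 and 235 CPM) and TNFRSF18, which encodes the co-stimulatory receptor GITR (151 and 255 CPM), were among the highest ratios.

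Proliferation genes were also higher in the obese NK sort, with 11 of 11 members higher and a median of 1.31. CENPF, a centromere protein of dividing cells, stood at 34.9 CPM (32.7 to 37.2) and 103 CPM (98.5 to 107), STMN1 at 98.5 and 247 CPM, TUBB at 89.6 and 199 CPM, and TUBA1B at 266 and 446 CPM. An unnamed cluster led by proliferation genes held 1.27% of lean and 4.23% of obese cells, and within NK-like cells, which leave it out, the median was 0.17. The other highest ratios were those of MYOM2 (54.2 and 155 CPM), SOX4 (52.9 and 115 CPM), SPRY1 (58.9 and 114 CPM) and HLA-DRA (103 and 183 CPM). Another unnamed cluster, led by the haemoglobin genes HBA1 and HBA2 beside NK genes, held 0.0926% of lean and 5.68% of obese cells.

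Myeloid markers were higher in the obese NK library. The macrophage core list was higher by a median of 2.44 and the perivascular macrophage list by 1.76, from low levels: C1QA, a complement gene of macrophages, stood at 0.149 and 17.4 CPM. The lipid-associated macrophage (1.71), inflammatory myeloid (1.58), monocyte (0.81), conventional DC identity (0.57) and MHC class II presentation (0.50) lists were higher too. Within NK-like cells the macrophage core median was -0.21, the perivascular one -0.23, the MHC class II one -0.02 and the lipid-associated one 0.04. T cell-like cells were 0.579% of the lean and 2.33% of the obese sort, although the T cell markers summed to 384 CPM in the lean and 335 CPM in the obese library.

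The lowest ratios in the obese NK library belonged to metallothionein genes, which bind zinc and copper, and to heat shock genes. MT2A stood at 5490 CPM in the lean and 782.8 CPM in the obese library, MT1X at 1834 and 36.7 CPM, and all 7 metallothionein members were lower (median -5.61, percentile 0). HSPA6 (187 and 7.39 CPM), HSPA1A (614 and 73.6 CPM), HSPA1B (286 and 26.8 CPM) and DNAJB1 (519 and 186 CPM) encode chaperones of the heat shock response. MT1F, the zinc exporter gene SLC30A1, MTRNR2L8 and IFITM1, an antiviral membrane protein gene at 214 and 61.5 CPM, complete the lowest. Clusters led by heat shock and metallothionein genes held 9.24% (8.39 to 10.1) of lean and 0.0778% of obese cells. Without them the metallothionein median was -2.74 and the immediate early and heat shock median was 0.13 rather than -0.26. DC maturation (median 0.31, 7 of 10 members higher) and mitochondrial transcripts (0.28, 10 of 11) were higher and interferon response (-0.20, 5 of 15) lower. The other medians were TGF-beta response 0.28 with 5 of 9 members higher, oxidative phosphorylation -0.07, cytokines and chemokines -0.03, fatty acid oxidation 0.13, hypoxia and glycolysis 0.11, ILC2 identity 0.06 and ribosomal proteins 0.02.

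In the CD200R-positive ILC sort, the same question concerns the helper-like innate lymphocytes. ILC2 genes hardly differed between the libraries, while ILC3 genes were higher in the obese one. The ILC2 identity list had a median of -0.07 with 4 of 11 members higher (percentile 8.24). GATA3, the transcription factor that directs type 2 lymphocytes, stood at 335 and 266 CPM, the interleukin 33 receptor gene IL1RL1 at 147 and 173 CPM, and RORA at 485 and 503 CPM. The ILC3 identity list had 12 of 12 members higher, with a median of 0.83 at percentile 100. Its most abundant members were LTB at 513 and 567 CPM, the stem cell factor receptor gene KIT at 324 and 473, the aryl hydrocarbon receptor gene AHR at 149.9 and 222, and IL1R1 at 141 and 198. Within ILC-like cells the ILC3 median was 0.93, and the ILC2 median came to 0.01 when cells were thinned to equal depth. The make-up of ILC-like cells differed too. A cluster led by PCDH9, LST1 and DLL1, with IL1R1 and IL23R among its leading genes, held 19% of them in the lean and 43.7% in the obese library. A cluster led by TMPRSS11E and NEB held 39.7% and 25.9%. How far this mix accounts for the higher ILC3 genes was not tested.

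The highest ratios in the obese ILC library included RGS1, a regulator of chemokine receptor signalling, at 230.3 CPM (224 to 237) and 573 CPM (562 to 584), CD83 at 152 and 354 CPM, the Notch ligand gene DLL1 at 37.4 and 102 CPM, and the death receptor gene TNFRSF25 at 59.3 and 121 CPM. LST1 (71.1 and 151 CPM), PCDH9 (54.7 and 111) and CAT (51.4 and 103) were higher too. MT-CO3 and MT-ND1 were higher by 0.97 and 0.87, and all 11 mitochondrial transcripts were higher (median 0.67). The median share of mitochondrial UMIs per kept cell was 3.45% in the lean and 5.64% in the obese library. The proliferation list was higher by 0.67 with 11 of 11 members. AREG, an epithelial growth factor gene of the ILC core list, stood at 3291 and 4589 CPM, although the ILC core list's median was 0.05 and turned to -0.01 with TMM scaling.

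Among the lowest in the obese ILC library were again MT1X (737 and 21.3 CPM), MT2A (2496 and 336 CPM) and the heat shock genes HSPA6, HSPA1A, HSPA1B, DNAJB1, HSPH1 and HSPD1, with HSPA1A at 931 and 66.2 CPM. The metallothionein median was -3.68, and the immediate early and heat shock list was lower in 14 of 16 members (median -0.43). Clusters led by these genes held 12% of lean and 0.0715% of obese cells, and without them HSPH1 and HSPD1 had log2 ratios of 0.07 and 0.03. MTRNR2L8 and TNFRSF9, the co-stimulatory receptor 4-1BB, were lower by log2 ratios of -2.37 and -1.15. DC maturation was lower (-0.28, 4 of 11 members higher). Cytokines and chemokines had a median of -0.23 with 6 of 13 members higher, and of 0.14 within ILC-like cells. Cytotoxic effector genes had a median of -0.13, and 0.03 within ILC-like cells. Macrophage lists were higher in this library as well, with macrophage core at 0.60 (0.07 within ILC-like cells), perivascular macrophage at 0.45, inflammatory myeloid at 0.43 and lipid-associated macrophage at 0.35, but not the monocyte (-0.02) and conventional DC identity (-0.10) lists.

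In the dendritic cell sort, the comparison asks whether the maturation state and type of adipose dendritic cells differ with donor condition. The DC maturation list was slightly higher in the obese library, with a median of 0.10 and 10 of 15 members higher (percentile 98.9). Its main members barely differed: CD83 stood at 807 and 797 CPM, CCR7, the receptor that guides mature dendritic cells to lymph nodes, at 304 and 315, and CD86 at 212 and 213. The median was 0.04 within dendritic-like cells and -0.01 without clusters led by heat shock and metallothionein genes. The conventional DC identity list (median -0.03) and the MHC class II presentation list (median 0.02) lay near 0, and TMM scaling took the former to 0.00. FCER1A stood at 590.4 and 489 CPM, CLEC10A at 389 and 474, and CD74, the class II invariant chain, at 6643 and 7238.

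Macrophage and lipid-handling genes were higher in the obese dendritic cell sort. The lipid-associated macrophage list was higher in 17 of 17 members with a median of 0.78, the macrophage core list in 13 of 14 with 1.003, and the perivascular macrophage list in 11 of 12 with 1.68, all at percentile 100. FABP4, a fatty acid binding protein, stood at 600 CPM (593 to 607) and 1069 CPM (1061 to 1077) over the whole sort. Within dendritic-like cells it stood at only 19.7 and 50 CPM, so the whole-sort values come mainly from other cells. The scavenger receptor gene CD163 stood at 36.4 and 129.9 CPM, the mannose receptor gene MRC1 at 147 and 258, and CTSD at 66.1 and 141. Macrophage-like cells were 1.75% (1.33 to 2.25) of the lean and 6.35% (5.59 to 7.19) of the obese sort, and most of them belonged to a cluster led by SPP1, APOE and TREM2 (1.63% and 5.03%). Within dendritic-like cells the medians were 0.34, 0.54 and 0.57 in the same order. VCAN (73.7 and 231 CPM) and the monocyte list (median 0.31) were higher. Monocyte-like cells were 3.38% (2.79 to 4.05) of the lean and 9.19% (8.28 to 10.2) of the obese sort. These whole-sort values are thus not those of dendritic-like cells alone. The chemokine genes CXCL3 (254 and 537 CPM) and CXCL2 (263 and 447 CPM), the lipoprotein receptor gene OLR1, CRIP1 and AC020656.1 complete the highest ratios. The inflammatory myeloid list was higher by 0.21 in the whole sort and lower within dendritic-like cells (-0.19).

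The lowest in the obese dendritic cell library were MT1G (208 and 6.35 CPM), MT1E (179 and 9.05), MT1X (430.5 and 31.4), SLC30A1, MTRNR2L8 and the heat shock genes HSPA6, HSPA1B, HSPA1A, DNAJB1 and HSPD1. The metallothionein median was -3.81, and clusters led by these genes held 13.7% of lean and 0.324% of obese cells. Interferon response genes had a median of -0.03, with 0.01 under TMM scaling and 0.26 within dendritic-like cells. Cytotoxic effector genes had a median of -0.44 over the whole sort, with FCGR3A, an IgG receptor gene, at 106 and 60.7 CPM. ILC-like cells were 1.42% of the lean and 0.297% of the obese sort, and the NK markers summed to 126 and 72.8 CPM. This median is thus not a value of dendritic-like cells alone. An unnamed cluster led by LYPD2 and FCGR3A held 13.5% of the lean and 6.84% of the obese sort.

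In the macrophage sort, the comparison asks whether lipid-associated macrophages, which appear in expanding fat, or other macrophage programs differ with donor condition. Inflammatory genes were higher in the obese library, while lipid-associated genes showed no common direction over the whole sort. All 15 measured members of the inflammatory myeloid list were higher, with a median of 1.34 at percentile 100, and 1.29 within macrophage-like cells. The make-up of macrophage-like cells differed too. A cluster led by CCL3L1 and EGR1 held 21.1% of them in the lean and 41.3% in the obese library. Its leading genes include CCL3, TNF and CCL4 of the list, so it was grouped partly by the genes compared. A cluster led by TTN and RNASE1 held 66.4% and 34.1%. CXCL8, the neutrophil chemokine interleukin 8, stood at 2656 CPM (2629 to 2683) in the lean and 10947 CPM (10916 to 10979) in the obese library. CXCL3 stood at 1529 and 3884 CPM, the growth factor gene EREG at 1311 and 3261, TNF at 41.4 and 178, and IL1B at 5018 and 6024. The lipid-associated macrophage list had a median of 0.14 with 9 of 17 members higher (percentile 96.5). FABP4 stood at 1764 and 1228 CPM in the whole sort but at 2261 and 2574 CPM within macrophage-like cells, beside an endothelial-like share of 5.2% and 0.495%. PLIN2, a lipid droplet coat protein, stood at 879 and 1139.7 CPM and CTSB at 743 and 834. A macrophage-like cluster led by SPP1, APOE and TREM2, marks of the lipid-associated type, held 3.87% (3.16 to 4.69) of lean and 8.45% (7.45 to 9.54) of obese cells of the sort.

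The lipid-associated median ranged from 0.03 within macrophage-like cells to 0.36 with cells thinned to equal depth, 0.41 with cells weighted equally and 0.45 with TMM scaling. TMM scaling shifted the obese-lean ratios of this sort by up to 0.31, and by less for genes of low level. The median over all measured genes was -0.20, so list medians near these values have no fixed direction. That holds for the perivascular macrophage list (-0.16, and 0.15 with TMM), fatty acid oxidation (-0.24 and 0.06), oxidative phosphorylation (-0.13 and 0.18), TGF-beta response (-0.15 and 0.14), proliferation (-0.07 and 0.17), NK tissue residency (-0.24 and 0.05) and cytotoxic effector genes (-0.14 and 0.10). Macrophage core genes had a median of 0.17, and -0.28 within macrophage-like cells. CD163 was higher (467 and 766 CPM), while C1QA stood at 765 and 689 and RNASE1 at 1038 and 601.

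The other highest ratios of the obese macrophage library were the transcription factor gene CEBPB at 327 and 1432 CPM, the chemokine genes CCL20 (281 and 1169 CPM), CCL3L1 (90.2 and 603), CXCL1 (35.3 and 158) and CXCL5 (25 and 102), the phosphatase gene DUSP2 (198 and 794), SDS (26.8 and 105) and IL10, an anti-inflammatory cytokine, at 79.6 and 309 CPM. TNF and NF-kB targets, which share CXCL2, CXCL3 and CCL20 with the inflammatory list, were higher in 12 of 14 members (median 0.57). Among them was NFKBIA at 2718 and 4933 CPM. The lymphocyte cytokine and chemokine list, which shares TNF, CCL3 and CCL4 with the inflammatory list, had a median of 0.40. Monocyte-like cells were 18.3% and 43.4% of the sort, but their main cluster was led by CCL20, IL1A and IL1B, genes that differ between the libraries, so these shares are not compared. The monocyte list had a median of 0.03, and 0.78 within macrophage-like cells, and LYZ stood at 1635 and 3813 CPM.

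The lowest ratios were those of MT1G (692 and 10.4 CPM), MT1E, MT1M, MT1X (1031 and 70.2 CPM), MTRNR2L1, the haem-degrading enzyme gene HMOX1 (447 and 122 CPM) and HSPD1 (735 and 184 CPM), with a metallothionein median of -4.00. A cDC2-like cluster led by heat shock and metallothionein genes held 14.7% (13.3 to 16.1) of lean and 0.106% of obese cells. ADIRF, RBP7 and SPTBN1 had log2 ratios of -2.64, -2.64 and -2.10 beside an endothelial-like share of 5.2% (4.37 to 6.13) in the lean and 0.495% (0.271 to 0.83) in the obese sort. Within macrophage-like cells these 3 genes had ratios of -0.25, -0.39 and -0.60. Interferon response genes were lower in 12 of 15 members (median -0.53, and -0.02 within macrophage-like cells), with IFI27 at 155 and 16.3 CPM. Lists of lymphoid programs were lower, with ILC2 identity at -0.69, ILC core at -0.59 and ILC3 identity at -0.51, but some members are abundant in this sort, such as NRP1 at 123 and 61.9 CPM and MAF at 99.1 and 65.2, and AREG was higher at 2979.9 and 3923 CPM. Conventional DC identity genes had a median of -0.34, at percentile 9.4 and so inside the random range. The cDC2-like share, which includes the stress-led cluster, was 23.1% in the lean and 5.16% in the obese sort. Immediate early and heat shock genes had a median of -0.60, hypoxia and glycolysis genes 0.08, mitochondrial transcripts 0.11 and ribosomal proteins 0.05.

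**Figure D2:**
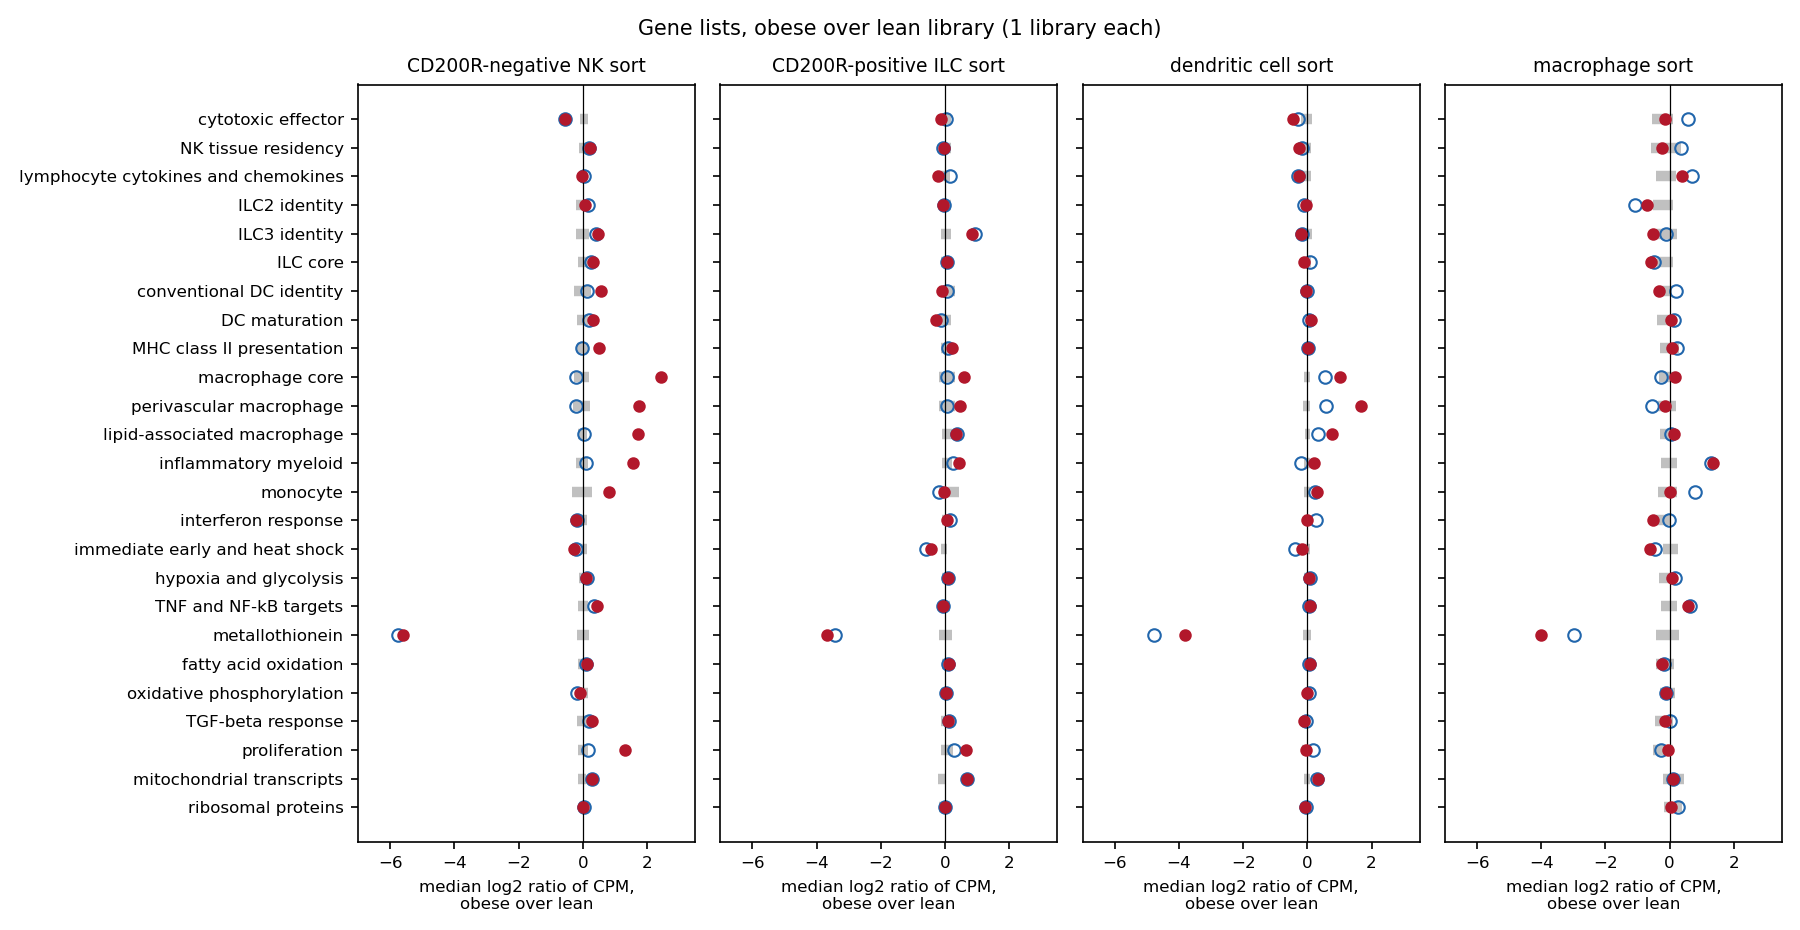
Median log2 ratio of CPM, obese over lean, of the 25 gene lists in each sort, for all kept cells (filled red) and for the sort's own cell class (open blue), with the central 95% of 10000 random lists as grey bars. Metallothionein genes lie far left in all 4 sorts (-5.61 to -3.68), and the inflammatory myeloid list lies at 1.34 in the macrophage sort.

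**Figure D3:**
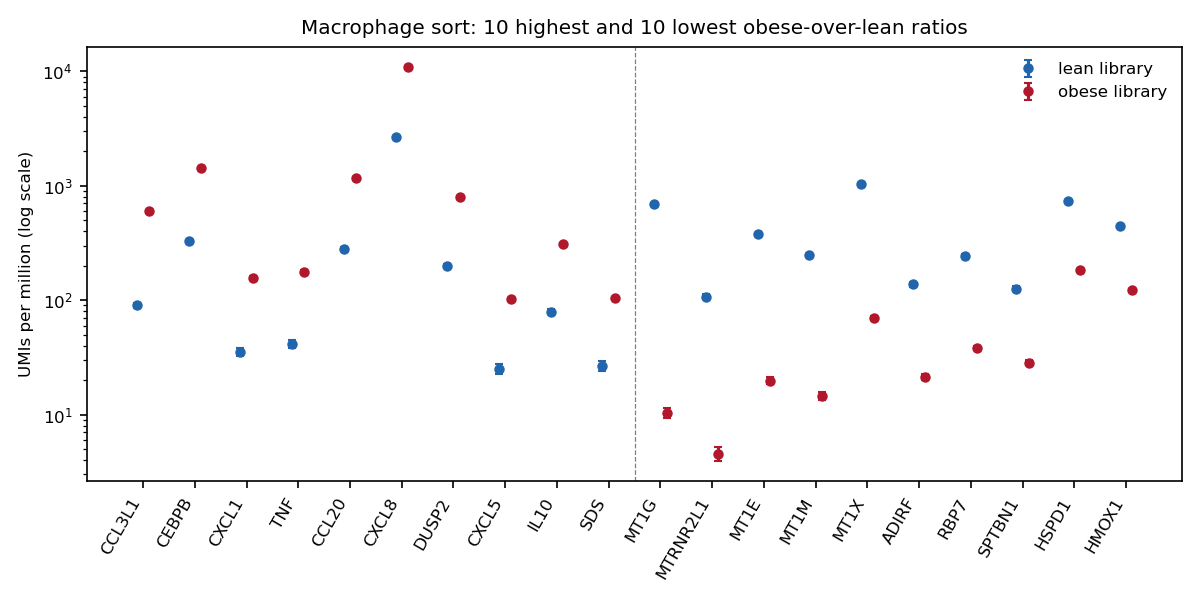
CPM on a log axis of the 10 genes with the highest and the 10 with the lowest obese-over-lean ratios in the macrophage sort, with exact Poisson 95% intervals and 1 library per dot. CXCL8 stands at 2656 CPM in the lean and 10947 CPM in the obese library, and MT1G at 692 and 10.4 CPM.

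Between the lymphoid sorts, the comparison asks what sets CD200R-positive ILCs apart from CD200R-negative NK cells in the same donor condition. ILC genes were higher and cytotoxic genes lower in the CD200R-positive sort. All 14 members of the ILC core list were higher, with a median log2 ratio, positive over negative, of 2.44 in the lean and 2.52 in the obese libraries, both at percentile 100. All 13 cytotoxic effector members were lower, with medians of -5.31 and -4.38. The ILC2 identity list had medians of 2.28 and 2.20 with 11 of 11 members higher, and the ILC3 identity list 2.66 and 2.89. IL7R stood at 519.9 CPM in the negative and 3245 CPM in the positive lean library.

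The 10 genes highest in the positive sort in both conditions were SLAMF1, IL1RL1, IL1R1, KIT, PTGS2, HPGD, LTB, AQP3, INPP4B and CFAP36. SLAMF1, a receptor of lymphocyte contacts, stood at 0.297 CPM (0.128 to 0.586) in the negative and 209 CPM (203 to 215) in the positive lean library, and KIT at 21.7 and 324 CPM. The 10 lowest were FGFBP2, FCGR3A, CCL3, GZMM, KLRF1, CCL4L2, NKG7, PYHIN1, GZMB and GZMH. NKG7 stood at 2934 CPM in the negative and 56.9 CPM in the positive lean library, and at 1987 and 38.5 CPM in the obese ones. NK tissue residency had medians of -0.44 and -0.53 and lymphocyte cytokines and chemokines -0.46 and 0.16. TMM shifted the ratios by up to 0.30 in the lean and 0.20 in the obese pair, and the medians over all measured genes were -0.27 and -0.21.

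Between the myeloid sorts, the comparison asks what sets dendritic cells apart from macrophages. All 14 conventional DC identity genes were higher in the dendritic cell sort, with a median log2 ratio, dendritic over macrophage, of 1.56 in the lean and 1.69 in the obese libraries, both at percentile 100. Within each sort's own class the medians were 2.59 and 2.62. All 14 macrophage core genes were lower (-2.44 and -2.17), as were all 12 perivascular macrophage genes (-4.87 and -3.41). The lipid-associated macrophage list had medians of -1.89 and -0.91 and the inflammatory myeloid list -2.001 and -2.93. DC maturation was higher (0.64 and 0.86). MHC class II presentation had medians of 0.33 (8 of 11 members higher, percentile 92.1, inside the random range) and 0.48 (9 of 11, percentile 99.4), with HLA-DRA at 13614 CPM in the dendritic cell and 7419 CPM in the macrophage lean library.

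Among the genes highest in the dendritic cell sort in both conditions were CLEC9A, S100B, DNASE1L3, IDO1, WDFY4, CPNE3, DAPP1, GPR157 and C1orf54. CLEC9A, a receptor for dead cells on type 1 conventional dendritic cells, stood at 0.777 CPM (0.388 to 1.39) in the macrophage and 115 CPM (112 to 118) in the dendritic cell lean library. The lowest were RNASE1, SELENOP, LYVE1, STAB1, FOLR2, C1QC, LILRB5, S100A8, PLTP and AQP9. LYVE1, a hyaluronan receptor of perivascular macrophages, stood at 345 and 1.58 CPM in the lean and 338 and 21.6 CPM in the obese macrophage and dendritic cell libraries. SELENOP stood at 1032 and 4.48 CPM in the lean and 1101 and 59.9 CPM in the obese pair. TMM shifted the ratios by up to 0.38 in the lean and 0.13 in the obese pair, and the medians over all measured genes were -0.24 and -0.08.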

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

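Chosen only after the result was seen were the tests below of free RNA, another cell type, a dissociation response and handling for the metallothionein genes, and the test of other cell types for the inflammatory genes.

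The ILC3 identity list differed between sorts in its direction: it was higher in the obese library of the CD200R-positive ILC sort (median log2 ratio 0.833) and lower in that of the macrophage sort (-0.511), and the difference itself was not tested. Within each sort's own class the medians were 0.93 and -0.11. The mix of ILC-like clusters differed between the lean and obese libraries as well, and its part in the first value was not tested. In the macrophage sort 3 of the 8 measured members of the list were higher, among them AHR at 83.6 and 213 CPM. TMM scaling shifted ratios of that sort by up to 0.31. The list's median was 0.479 in the NK sort and -0.192 in the dendritic cell sort, where thinning to equal depth turned it to 0.1633.

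Metallothionein genes were lower in the obese library of all 4 sorts. Free RNA in the lean suspensions would spread these UMIs over cells by depth. The 10% of cells richest in them held at least 2.77 times the share that depth gives in the 4 lean libraries. Free RNA was thus not their only source there. The same measure was 2.44 to 3.2 in the obese libraries, so it cannot tell whether free RNA added to the difference. After thinning to equal depth the median nearest 0 was -3.85, and within each sort's own class it was -2.99, so neither depth nor another cell type accounts for the whole difference. A dissociation response stays open: heat shock genes were lower in the NK, ILC, dendritic cell and macrophage sorts (medians -2.26, -2.53, -1.91 and -1.27), while immediate early genes were lower in the ILC sort (-0.248, 8 of 10 members) and near 0 in the others. Handling or exposure that differed between lean and obese material, such as zinc or heat, and donor condition itself cannot be told apart, because all 4 sorts show the same direction and each group is 1 library.

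Cytotoxic effector genes were lower in the obese CD200R-negative sort. Other cell types in that sort would leave NK-like cells without a difference, but their median was -0.563. NK-like cells leave out the unnamed cluster led by HBA1 and HBA2, which has FGFBP2, GZMH and FCGR3A among its leading genes. Over all kept cells, which include that cluster, the median was -0.556. Depth would bring the thinned median near 0, but it was -0.486. The make-up of NK-like cells differed as well: clusters led by ABI3 and FGFBP2 and by CCL4L2 and CCL3L1 held 27.1% and 22.9% of them in the lean and 13.5% and 11.6% in the obese library, and a cluster led by GZMK and TIGIT 19.6% and 49.6%. A different mix of NK subsets or a difference of NK cell state with donor condition stay open as hypotheses, beside differences in donors, sort gates or handling that 1 library per group leaves untested.

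Inflammatory myeloid genes were higher in the obese macrophage sort. After thinning the median was 1.43, which argues against depth as the whole account. Within macrophage-like cells it was 1.29, but monocyte genes were higher in these cells too (median 0.78), so other cell types stay open. The mix of macrophage-like clusters differed as well. The cluster led by CCL3L1 and EGR1 held 21.1% of these cells in the lean and 41.3% in the obese library. Its leading genes include CCL3, TNF and CCL4 of the list, and the part of this mix in the difference was not tested. Free RNA in the obese suspension stays open: the difference in summed CPM in dendritic-like cells was 0.244 of that in macrophage-like and monocyte-like cells, but these cells were grouped partly by the same genes. Activation with donor condition or during preparation was not tested and stays open too.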

How the results depend on the processing

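The values without stress-led clusters (those led by heat shock and metallothionein genes) and from clustering without stress genes were chosen after the data were seen, as was the share of the cluster led by SPP1 and TREM2. No paired analysis was possible because each group holds 1 library, and no replicate could be left out. Values are median log2 ratios unless stated, and the cause was not tested for any of them. The main values were -0.556 for cytotoxic effector genes in the NK sort, -0.0745 for ILC2 identity in the ILC sort, 0.101 for DC maturation in the dendritic cell sort, 0.142 for lipid-associated macrophage genes in the macrophage sort, 2.444 and 2.521 for ILC core between the lymphoid sorts (lean, obese) and 1.557 and 1.687 for conventional DC identity between the myeloid sorts (lean, obese). Across all alternatives, 39 values of these lists stayed within counting error, 32 moved and 1 reversed. Having no minimum count left all of them the same.

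With TMM scaling, conventional DC identity was 1.922 (lean) and 1.811 (obese), ILC core 2.74 and 2.713, DC maturation 0.1341 and lipid-associated genes 0.4463. With totals without mitochondrial and ribosomal protein genes, these were 1.692 and 1.799, 2.558 and 2.66, 0.118 and 0.179. With all barcodes, lipid-associated genes were at 0.1004. With cells weighted equally, NK cytotoxic genes were at -0.4637, conventional DC identity at 1.661 (lean) and 1.795 (obese), ILC core at 2.646 (lean) and lipid-associated genes at 0.4063. With thinned cells, ILC core was 2.646 (lean), conventional DC identity 1.863 (obese), ILC2 identity 0.01193, NK cytotoxic genes -0.4861 and lipid-associated genes 0.3639. Thinning also turned cytokines (0.009664) and ILC3 identity (0.1633) in the dendritic cell sort and cytotoxic genes in the ILC sort (0.003589).

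Within the own class, conventional DC identity was 2.589 (lean) and 2.619 (obese), DC maturation 0.03833 and lipid-associated genes 0.02774. Among lists outside the random range in all kept cells, the direction turned for inflammatory genes in the dendritic cell sort (-0.193), for macrophage core (-0.2129), MHC class II (-0.02399) and perivascular genes (-0.2251) in the NK sort, and for cytokines (0.1412) and cytotoxic genes (0.03078) in the ILC sort. With a pseudocount of 10 CPM, ILC core was 2.049 (lean) and 1.975 (obese) and conventional DC identity 1.253 and 1.316. Without stress-led clusters, lipid-associated genes were at 0.104, and the direction turned for DC maturation (-0.007233), for the immediate early and heat shock list (0.1326) and DNAJB1 (0.07422) in the NK sort, and for HSPH1 (0.07273) and HSPD1 (0.02736) in the ILC sort.

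The own-class share differed by -10.95 percentage points in the NK sort, and by -12.25 at resolution 2.0, -3.826 with all 8 libraries clustered together and -13.05 with doublet calls kept. In the macrophage sort the difference of 2.99 points turned to -6.484 at resolution 0.5 and to -5.755 with all libraries together, and was 16.02 when stress genes were left out of the clustering. Over all shares 14 stayed, 4 moved and 2 reversed. Reversed here counts only lists whose main median lay outside the central 95% of random lists. Of the 1129 alternative medians run, for 126 pairs of list and comparison, 61 had another sign than the main value, 13 of them with TMM scaling and 17 within the own class. Of the other lists 648 values stayed, 399 moved and 10 reversed, and of the named genes 155 stayed, 162 moved and 3 reversed. A few myeloid lists could not be computed in thinned lymphoid cells. The cluster led by SPP1 and TREM2 held 3.48% to 3.99% of lean and 7.39% to 9.06% of obese macrophage-sort cells over all 6 clusterings. Median UMIs per kept cell were 5402.5 and 15822 in the lean and obese macrophage sorts, so genes of low level are seen less well in the lean one.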

Other observations

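Across genes, which are not replicates, the Spearman correlation of the obese-lean log2 ratios was 0.392 between the dendritic cell and macrophage sorts (2174 genes), 0.31 between the NK and ILC sorts (2232 genes) and 0.309 between the ILC and dendritic cell sorts (1785 genes). It was 0.128 between the NK and dendritic cell sorts, 0.0353 between the ILC and macrophage sorts and -0.0106 between the NK and macrophage sorts. Without the heat shock, metallothionein, immediate early and related stress genes, the first 3 were 0.376, 0.296 and 0.29. The Pearson correlations of the same 3 pairs were 0.532, 0.713 and 0.747 with these genes and 0.394, 0.306 and 0.339 without them.

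Plasmacytoid dendritic-like cells, the main producers of type I interferon, were found in the NK sort at 0.37% of lean and 1.09% of obese cells. Mature dendritic-like cells were 4.7% and 5.49% of the dendritic cell sort, and cDC1-like cells, which cross-present antigen to killer T cells, 20.3% and 19.5%. The endothelial tight junction gene CLDN5 stood at 272 CPM in the lean and 19.3 CPM in the obese macrophage sort.

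The median share of mitochondrial UMIs per kept cell was 6.25% and 7.49% in the lean and obese NK sorts, 5.65% and 7.06% in the dendritic cell sorts, and 6.83% and 7.1% in the macrophage sorts.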
